A study of Mus musculus with 2 samples.

How the data were processed

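The series measured single-cell RNA in tongue tumours of C57BL/6 mice. The tumours were induced with 4NQO, a chemical carcinogen, and the mice then received an antibody against CD276 or a control antibody for 4 weeks. It held 2 libraries made with a 10x Genomics 3′ single-cell kit, 1 for each antibody, and each group therefore had 1 library and no replicate. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 3.1.5 and the mouse build mm10 were used, with no role or parameters given for them. The deposited matrix of the anti-CD276 library held raw counts of unique molecular identifiers (UMIs) per gene and barcode, before any selection of cells. The control library's lists of barcodes and features held no counts and were not used here, so no treated library was compared with a control library.

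The matrix held 31053 genes and 6794880 barcodes, of which 1261828 had at least 1 UMI, with 74081656 UMIs in all. Cells were barcodes with at least 500 UMIs (24336 barcodes), at least 300 genes (7906 left) and at most 20% mitochondrial UMIs (7499 left). Each of these was tested against the RNA profile of barcodes with 1 to 100 UMIs by a Monte Carlo multinomial test with 2000 draws and at most 5000 UMIs per barcode. Barcodes with a Benjamini-Hochberg false discovery rate of at most 1% were kept (3564 left). Scrublet scores were computed, its automatic threshold marked under 0.5% of the barcodes, and the 105 top-scoring barcodes, the share expected at 0.8% per 1000 barcodes (2.85%), were removed as doublets. The 3459 cells left held 36260881 UMIs and a median of 5575 UMIs, with quartiles of 1882 and 14727 and a range from 538 to 107316. Free RNA was also read from 39123 barcodes of 200 to 450 UMIs with a median of 396 UMIs, called empty droplets here. They were part of a plateau that reached beyond 450 UMIs, as 65660 barcodes had 300 to 600 UMIs. Shares of free RNA that rest on their median may therefore be too low.

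The analysis used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and scikit-learn 1.9.0. Counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes and 30 principal components were taken, and cells were clustered with the Leiden method (20 neighbours, resolution 1, seed 1). The genes of the 15 result lists were left out of the clustering genes, so that a list did not define the clusters in which it was then measured. Clusters were still partly defined by other genes of the same programmes, such as Oasl2 and Trim30a for interferon response and histone genes for the cell cycle. Clusters were named from 24 marker sets by the mean scaled expression of each set, and keratinocyte, T and macrophage clusters were clustered again, keratinocyte and T clusters being named from 9 further sets and macrophage clusters from the first 24. A name needed a score of at least 0.3 (0.1 at the second level), a lead of 0.2 over the next set and 3 markers each seen in at least 10% of the cells. The 10 genes most enriched in a cluster could not hold more markers of another set, and a cluster with a median below 1858 UMIs (the median of all cells divided by 3) needed a marker of its own set among them. These naming thresholds were set after the clusters had been seen, and 3 clusters with 6.79% of the cells stayed unnamed. Names are written as keratinocyte-like and so on, because they rest on markers alone.

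The marker sets, the result lists, the comparisons, the settings and most alternatives were chosen before the data were examined. The lists were B7-family and checkpoint ligands, T cell checkpoint and costimulatory receptors, cytotoxic effectors, T cell memory and naive genes, squamous stem and progenitor genes, partial epithelial-mesenchymal transition (EMT) and invasion, AP-1 factors, antigen presentation by major histocompatibility complex (MHC) class I and by class II, interferon response, chemokines and cytokines, proliferation, dissociation stress, oxidative and xenobiotic defence, and hypoxia and glycolysis. Of their 252 genes, Cd244a and Cxcl11 were not among the features, which left 250, and the marker Lamb4 was not among them either. Cells with Xist UMIs only and cells with UMIs of Ddx3y, Uty, Kdm5d or Eif2s3y only were separated after the data were seen, as cells of female and male mice. Gene positions were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names.

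Levels are CPM, the counts of a gene scaled to the summed UMIs of a class, with exact Poisson 95% intervals, shares have Clopper-Pearson 95% intervals, and ratios of CPM have exact conditional Poisson 95% intervals. With 1 library, cells are not replicates, so no p-value was computed; all intervals and limits cover counting error only, and a list member counted as higher or lower by size alone. It needed at least 20 UMIs over both classes and a CPM at least 2-fold apart. A gene with 0 UMIs on 1 side was set to a floor of 3 UMIs over the class for these counts and medians, and its fold is given as at least the value at that floor. Each list's median log2 ratio was also placed among 10000 random lists of genes matched in expression, as a description and not as a test. Shares of cells with a Cd276 UMI were taken after thinning every cell to 1000 UMIs, and Cd276-detected and undetected cells were compared after thinning to 2000 UMIs.

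In each comparison of classes and each list, the 3 members with the highest and the 2 with the lowest ratio among those at least 2-fold apart were named. For levels over all classes, the 2 classes with the highest CPM of each list's top 3 members were named. Cd276, Bmi1, Cd44, Sox2, Vim, Mki67, Cd274, Pdcd1, Gzmb and Ifng were always reported. Where space was short, a part of the named genes is given, and genes outside this rule are marked in the text as chosen after their values were seen. The ratio of 1 gene in the comparison of Cd276-detected cells is not reported here.

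The size rule was tested on simulated counts, drawn as Poisson counts from the summed UMIs of each class. The draws held no spread between cells or clusters, so they measure counting error alone. That the intervals held the true ratio near 95% follows from the draw. Genes whose UMIs gather in a few cells or in 1 cluster were not simulated. With 12452 genes in the comparison of basal with suprabasal cells, 1.6% of the genes simulated as unchanged were called, 2% of those changed 1.5-fold, 98.0% of those changed 3-fold and 100% of those changed 4-fold or 8-fold, and the intervals held the true ratio for 95.5% of the unchanged genes. With 12956 genes in the comparison of fibroblast-like with keratinocyte-like cells, 6.82% of the unchanged genes were called, 10.4% of those changed 1.5-fold, 91.8% at 3-fold, 84% at 4-fold and 98.0% at 8-fold, and the intervals held the true ratio for 97.0% of the unchanged genes. The test against free RNA passed 4 of 1000 simulated empty barcodes and 500 of 500 simulated T-like cells with 30% free RNA. The simulated empty barcodes were drawn from the profile used in the test, so their low pass rate follows from the draw. Empty droplets of the plateau were not simulated. The gene Gm42418 made up 30.4% of their UMIs, against 7.89% in that profile. How many of them the test would pass is therefore not known.

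Alternatives chosen before the data were examined were a minimum of 1000 UMIs, a mitochondrial limit of 10%, no test against free RNA, doublets kept, resolutions of 0.5 and 2, the list genes left in the clustering, the mean of each cell's CPM, thinning to 1000 UMIs, and thinning to 1000 or 4000 UMIs for the Cd276-detected cells. Chosen after the data were seen were the empty-droplet plateau as the free RNA profile, subtraction of the expected free RNA, leaving Gm42418 and AY036118 out of the totals, cells of either sex alone, and leaving out each keratinocyte cluster in turn, also for the lists and single genes of the basal over suprabasal comparison and among the cells that a cluster was compared with, and, for the ratio between the endothelial clusters, leaving out the 5 endothelial-like cells with the most Cd276 UMIs. The share of RNA expected from empty droplets was their median UMIs over the median UMIs of the class, and a gene's expected free RNA was this share times its CPM in empty droplets. The comparison of CD8 T-like with other T-like cells, planned before the data were examined, had no value under the main settings, because no cluster was named CD8 T-like.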

Results

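The cells came from tongue tumours of C57BL/6 mice, a model of head and neck squamous cell carcinoma. The tumours were induced with 4NQO, a chemical carcinogen, and the mice received an antibody against CD276 or a control antibody for 4 weeks. CD276, also called B7-H3, is a cell-surface protein of the B7 family of immune ligands. The series held 2 libraries, 1 per antibody, and the matrix of the anti-CD276 library is the one analysed here, so no value compares treated with control mice. It held 74081656 UMIs (counted RNA molecules), of which 36260881 lay in 3459 cells with a median of 5575 UMIs and 2092 genes per cell. There were no replicates, and intervals are 95% intervals for counting error only. The number of mice is not given in the sources used here. Xist, the RNA of the inactive X chromosome, was seen without Y-linked UMIs in 600 cells and Y-linked UMIs without Xist in 1042, so ratios are also given within each of these sets, called Xist-only and Y-only cells.

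Which cell populations the treated tumours held was the question of the first comparison. Keratinocyte-like cells, the epithelial class that squamous tumours belong to, were the largest class with 1323 cells, 38.2% (36.6 to 39.9, Clopper-Pearson). T-like cells made up 11.7% (10.6 to 12.8), salivary or glandular epithelial-like cells 11.2% (10.2 to 12.3), blood endothelial-like cells 9.54% (8.58 to 10.6) and neutrophil-like cells 9.37% (8.42 to 10.4). Macrophage-like cells were 4.39% (3.74 to 5.13), fibroblast-like cells 3.41% (2.83 to 4.07) and mural-like cells, the contractile cells around vessels, 3.24% (2.67 to 3.88). Schwann-like cells (37), erythroid-like cells (20) and lymphatic endothelial-like cells (18) were rare, and no cluster was named for B cells, plasma cells or natural killer cells. Neutrophil-like, T-like and macrophage-like cells together were 879 cells, 25.4% (24.0 to 26.9). Of these, 88 neutrophil-like cells formed a cluster with a median of 769 UMIs and 51.5% of the RNA expected from empty droplets. Another 63, counted as macrophage-like, formed a shallow cluster led by epithelial genes. The neutrophil-like, macrophage-like and joint shares may therefore be too high. Y-only cells were 97.1% of the cells with a sex call among neutrophil-like cells, 72.1% among keratinocyte-like cells and 20.9% among salivary-like cells. Neither Xist nor Y-linked UMIs were seen in 254 of 324 neutrophil-like, 387 of 1323 keratinocyte-like and 267 of 387 salivary-like cells. Whether the classes differ in how well these genes are detected was not tested, so these shares may not be those of the animals. Without the test against free RNA the T-like share was 5.66%, and at a clustering resolution of 2 it was 7.43%; 3 clusters with 235 cells, 6.79% (5.98 to 7.68), stayed unnamed.

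**Figure D1:**
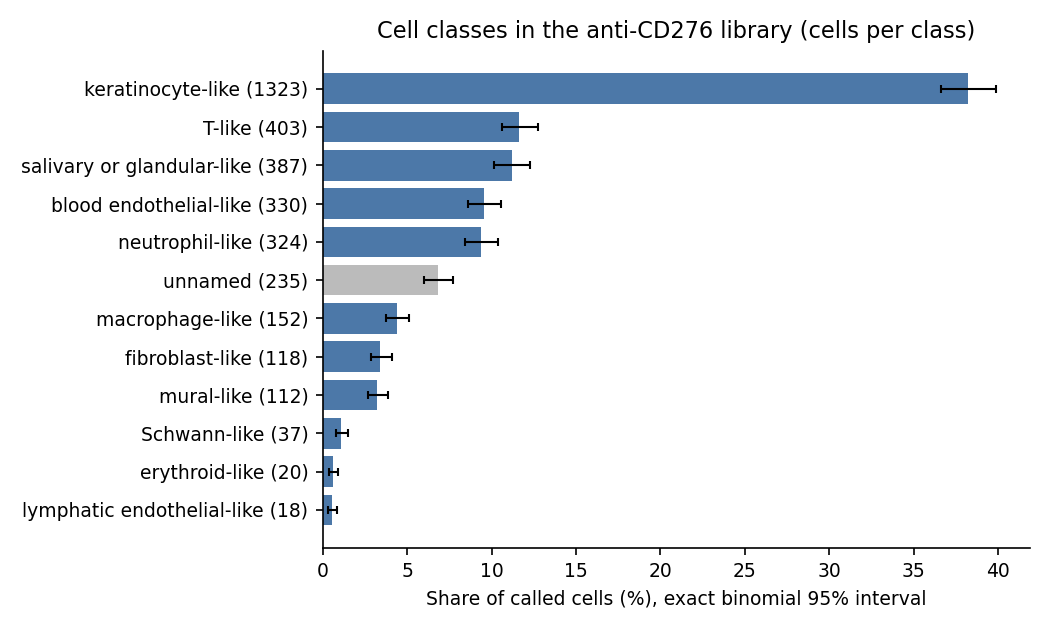
Share of the 3459 cells in each class, in percent of all cells on the horizontal axis, with Clopper-Pearson 95% intervals for counting error. Keratinocyte-like cells lead with 38.2%, and the unnamed clusters hold 6.79%.

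Where the target of the antibody was expressed was addressed by the level of Cd276 (ENSMUSG00000035914, GRCm38 chromosome 9, 58524298 to 58555437, minus strand) in each class. Cd276 was highest in blood endothelial-like cells, at 48.8 CPM (40.3 to 58.5), which was 4.66-fold (3.70 to 5.85) the 10.5 CPM (9.18 to 11.9) of keratinocyte-like cells. The ratio was 5.35 (3.88 to 7.30) among Y-only and 6.79 (4.03 to 11.6) among Xist-only cells. Mural-like cells had 18.3 CPM (10.7 to 29.3), macrophage-like cells 13.1 (5.66 to 25.8) and fibroblast-like cells 9.72 (4.198 to 19.2). The intervals of the fibroblast-like ratio over keratinocyte-like cells, 0.929 (0.396 to 1.86), and of the macrophage-like ratio, 1.25 (0.535 to 2.51), include 1. The fibroblast-like ratio was 1.06 (0.127 to 3.89; 2 UMIs) among Y-only and 1.44 (0.280 to 4.66; 3 UMIs) among Xist-only cells. Salivary-like cells had 4.92 CPM (3.36 to 6.94), T-like cells 2.67 (0.551 to 7.80; 3 UMIs) and neutrophil-like cells 1.85 (0.0469 to 10.3; 1 UMI), while empty droplets had 7.03 CPM. As a mean of each cell's CPM, which weighs all cells alike, the endothelial-like ratio over keratinocyte-like cells was 2.87.

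With every cell thinned to 1000 UMIs, Cd276 was seen in 3.30% (1.59 to 5.99) of blood endothelial-like cells, of which the median before thinning was 4979 UMIs. The share was 0.915% (0.474 to 1.59) in keratinocyte-like cells, with a median of 14550 UMIs, and 0.301% (0.00763 to 1.67; 1 cell) in T-like cells, a class not known for the gene, with a median of 2227 UMIs. The keratinocyte-like share thus lay within the interval of the T-like share, and the difference was not detectable at this depth. The lower bound of the endothelial-like share, 1.59%, lay below the upper bound of the T-like share, 1.67%.

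Within blood endothelial-like cells, 1 of the 2 clusters carried most of the Cd276 UMIs, a comparison added after the values were seen, as were the genes named for it. The cluster whose leading genes were Timp4, Col13a1, Dll4, Sema3g, Esm1 and Apln, a mix of genes known from arterial and capillary cells and from sprouting vessel tips (161 cells), had 67.5 CPM (54.7 to 82.5). The cluster marked by Sele, Selp and Ackr1, genes of venules that take up leukocytes (169 cells), had 20.3 CPM (12.2 to 31.7), a ratio of 3.33 (2.02 to 5.77). It was 6.42 (2.09 to 32.0; 3 UMIs in the venular cluster) among Y-only and 2.65 (1.26 to 5.97) among Xist-only cells, and 3.71 (1.99 to 7.54) without the 5 endothelial-like cells with the most Cd276 UMIs. With every cell thinned to 1000 UMIs, Cd276 was seen in 4.35% (1.77 to 8.75; 7 cells) of the first cluster, with a median of 6658 UMIs before thinning, and in 2.11% (0.438 to 6.05; 3 cells) of the venular one, with a median of 3051, and these intervals overlap. Between the same clusters Esm1 was 5.86-fold (5.22 to 6.59), Apln 6.56-fold (5.24 to 8.31) and Dll4 10.1-fold (6.94 to 15.3) higher, and of the checkpoint ligands Tnfsf9 was 12.5-fold (3.24 to 107; 2 venular UMIs) and Cd274, the gene of PD-L1, 4.45-fold (1.55 to 17.5) higher. Icosl, with 13 UMIs in all, had a ratio of 0.120 (0.0129 to 0.549; 2 UMIs in the first cluster), and other ligands such as Pvr (0.772, 0.480 to 1.25) and Cd47 (1.28, 1.13 to 1.45) were less than 2-fold apart. The cell cycle gene Mki67 was lower in it, with a ratio of 0.147 (0.0658 to 0.295).

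**Figure D2:**
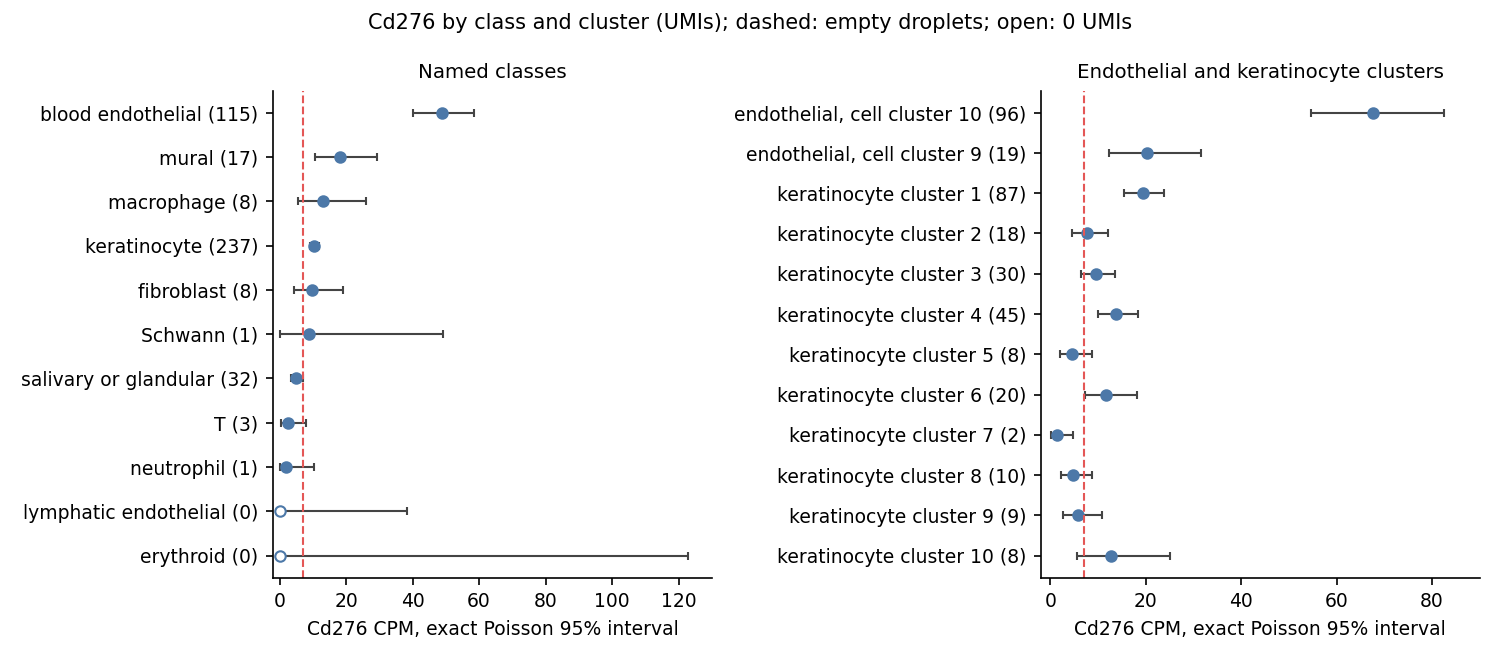
Cd276 in CPM with exact Poisson 95% intervals, by cell class and by endothelial and keratinocyte cluster, with the level of empty droplets as a line. Blood endothelial-like cells reach 48.8 CPM, and among the keratinocyte clusters the highest level is 19.3 CPM.

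Whether the antibody's target and programmes of stem cells, invasion and immunity differ between the basal layer, which holds the dividing progenitors of squamous epithelium, and the differentiating suprabasal cells was asked next. The comparison had 1044 basal and 247 suprabasal keratinocyte-like cells. The suprabasal cells formed keratinocyte clusters 7, 8 and 9, described below. The 10 leading genes of clusters 8 and 9 held no marker of the suprabasal set. Cluster 9 (54 cells) also had Mki67 at 480 CPM, near the 574 CPM of basal cluster 4. Whether the cells of cluster 9 were differentiating was not tested. Cd276 was 3.08-fold (1.96 to 5.08) higher in basal cells, at 12.4 CPM (10.8 to 14.2) against 4.02 (2.49 to 6.15), with ratios of 2.73 (1.64 to 4.84) among Y-only and 4.33 (0.689 to 180; 1 suprabasal UMI) among Xist-only cells. The basal clusters, described below, were not alike in Cd276. It ranged from 4.43 CPM (1.91 to 8.73; 8 UMIs) in cluster 5 to 19.3 CPM in cluster 1, which held 87 of the 208 basal UMIs. The suprabasal clusters ranged from 1.31 CPM (cluster 7) to 5.71 CPM (cluster 9). The suprabasal level lay below the 7.03 CPM of empty droplets. Of the RNA of suprabasal cells 2.4% was expected from empty droplets, so free RNA was expected to add only 2.4% of that 7.03 CPM. Pvr, a ligand of the receptor TIGIT, was the other of 2 of 8 B7-family and checkpoint ligands at least 2-fold higher in basal cells (2.12, 1.40 to 3.33). Cd274 had 9 basal and 5 suprabasal UMIs, with a ratio of 0.560 (0.168 to 2.13).

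Of 22 measured partial EMT and invasion genes, 10 were at least 2-fold higher in basal cells and 0 lower, with a median log2 ratio of 0.82. Mmp9, which degrades basement membrane collagen, had 251 UMIs in basal and 0 in suprabasal cells and was at least 26.0-fold higher, with 248 of the UMIs in cluster 1, 1 of the keratinocyte clusters described below. Mmp10 was 12.6-fold (4.22 to 62.1; 3 suprabasal UMIs) and the matrix protein gene Tnc 11.9-fold (8.23 to 17.8) higher, while Vim had a ratio of 0.828 (0.665 to 1.04). Without cluster 1, Mmp10 had a ratio of 0.850 (0.181 to 5.25; 3 suprabasal UMIs) and Tnc one of 8.58 (5.91 to 12.9); ratios of single genes without 1 cluster, here and below, were added after the values were seen. The count was 9 of 20 with 2 lower among Y-only and 11 of 17 with 1 lower among Xist-only cells. It was 4 of 20 with 2 lower when cluster 1 was left out, 14 of 22 with 0 lower when cluster 8 was left out and 6 at a minimum of 1000 UMIs per cell.

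Among 20 stem and progenitor genes, 6 were at least 2-fold higher in basal cells and 1 lower, with a median of 0.57; within the sexes the counts were 4 higher and 1 lower of 18 (Y-only) and 6 higher and 0 lower of 15 (Xist-only). The stem cell receptors Lgr5 and Lgr6 led with 16.5-fold (2.83 to 663; 1 suprabasal UMI) and 12.4-fold (2.11 to 503; 1 suprabasal UMI), and Aldh1a1 had a ratio of 3.01 (0.931 to 15.4; 3 suprabasal UMIs). Aldh1a3, an enzyme of retinoic acid synthesis, was 7.49-fold lower in basal cells (ratio 0.134, 0.0956 to 0.185). Single clusters carried part of this: without cluster 6 the ratio of Lgr5 was 3.46 (0.492 to 150; 1 suprabasal UMI), and without cluster 8 that of Aldh1a3 was 0.925 (0.479 to 1.96). Bmi1 (1.66, 1.27 to 2.19) and Sox2 (1.60, 1.42 to 1.82) were higher by less than 2-fold, and the ratio of Cd44 was 0.982 (0.929 to 1.04).

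Of 26 chemokines and cytokines, 9 were higher in basal cells and 3 lower, with a median of 0.59. Tgfb2 (5.92, 3.89 to 9.44), Cxcl5 (5.56, 3.51 to 9.35) and Tgfb3 (4.56, 2.33 to 10.2) led the basal side, and Arg1 (0.278, 0.229 to 0.337) and Il34 (0.440, 0.198 to 1.01) were lowest. Without cluster 3 the ratio of Cxcl5 was 1.31 (0.776 to 2.31), and without cluster 7 that of Il34 was 1.87 (0.443 to 16.7; 2 suprabasal UMIs). Of 19 interferon response genes, 4 were higher and 0 lower with a median of 0.08, among them Ifit3 (4.35, 1.78 to 13.8), Gbp2 (3.13, 1.84 to 5.73) and Cxcl9 (3.11, 1.57 to 7.02). These values rested on cluster 3, which held 61 of the 70 basal Ifit3, 120 of the 151 Gbp2 and 89 of the 90 Cxcl9 UMIs. Without it the ratios were 0.689 (0.207 to 2.62), 0.791 (0.415 to 1.58) and 0.0426 (0.000971 to 0.307; 1 basal UMI), and 0 of 16 interferon response genes were higher and 13 lower in basal cells, whereas without suprabasal cluster 9 18 of 19 were higher and 0 lower. Of 6 MHC class II genes, 3 were higher (H2-DMb1, Cd74 and H2-Eb1, with ratios of 3.15, 2.29 and 2.02) and 0 lower, at levels below those of empty droplets. Free RNA was expected to add 2.70 of the 7.44 CPM of Cd74 in basal and 2.30 of the 3.26 CPM in suprabasal cells, and 1.13 of 5.42 and 0.961 of 2.68 CPM of H2-Eb1. For H2-DMb1 it was 0.157 of 4.23 and 0.134 of 1.34 CPM. Without cluster 4 the ratio of Cd74 was 1.61 (0.940 to 2.92), and 1 of the 6 genes was higher. Of 14 MHC class I genes 0 were 2-fold apart. Of 5 T cell memory and naive genes, 3 were higher, which in keratinocytes are the Wnt pathway factors Lef1 (3.90, 2.11 to 7.99) and Tcf7 (3.29, 1.999 to 5.78) and the survival gene Bcl2 (2.43, 1.76 to 3.43); the ratio of Lef1 was 1.39 (0.708 to 2.99) without cluster 5. Of 3 cytotoxic effector genes measured, 2 were lower in basal cells, the chemokines Ccl4 (0.277, 0.203 to 0.377) and Ccl3 (0.361, 0.236 to 0.557), of which cluster 8 held 81 of 92 and 36 of 43 suprabasal UMIs. Without it their ratios were 1.38 (0.732 to 2.87) and 1.32 (0.596 to 3.45), and 0 genes were lower. Both genes lay below the empty droplets (86.8 and 48.2 CPM), and free RNA was expected to add 2.45 of 4.88 CPM of Ccl4 in basal and 2.08 of 17.6 in suprabasal cells, and 1.36 of 2.98 and 1.16 of 8.24 CPM of Ccl3. Of 3 T cell checkpoint and costimulatory receptors, Cd27 was lower (0.438, 0.260 to 0.745), with a ratio of 1.03 (0.474 to 2.56) without cluster 9.

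Of 20 proliferation genes, 0 were 2-fold apart (median fell by 0.14 on the log2 scale), and Mki67 had a ratio of 0.838 (0.777 to 0.904). The count depended on the clusters included, with 12 lower in basal cells without cluster 4 and 14 higher without cluster 9. Of the suprabasal Mki67 UMIs, 756 lay in cluster 9, against 63 in cluster 7 and 118 in cluster 8. Among Xist-only cells, with 22 suprabasal cells, 14 of the 20 were higher in basal cells. Of 9 AP-1 factors 0 were 2-fold apart (median 0.48), of 12 dissociation stress genes 1 was higher, Nr4a1 (2.88, 2.52 to 3.31), and of 12 hypoxia and glycolysis genes 1 was higher, P4ha1 (2.61, 2.24 to 3.07). Of 13 oxidative and xenobiotic defence genes, Ugdh (2.17, 1.88 to 2.51) was higher (1.82 without cluster 7 and 1.86 without cluster 8, with 0 of 13 higher in both cases), and the detoxifying enzymes Aldh3a1 (0.365, 0.328 to 0.406) and Gsta4 (0.383, 0.374 to 0.393) were lower in basal cells, at 0.850 and 0.435 without cluster 7. With each of clusters 1 to 9 left out in turn, the members higher in basal cells ranged from 0 to 5 for AP-1 factors, from 0 to 4 for dissociation stress, from 1 to 4 for hypoxia and glycolysis and from 0 to 3 for oxidative and xenobiotic defence. They ranged from 5 to 12 for chemokines and cytokines, from 0 to 5 for MHC class I, from 1 to 3 for checkpoint ligands, from 1 to 4 for T cell memory and naive genes and from 4 to 9 for stem and progenitor genes. T cell checkpoint and costimulatory receptors ranged from 0 to 2, and MHC class II genes from 1 to 4. Members lower in basal cells ranged from 0 to 2 for hypoxia and glycolysis and from 1 to 3 for oxidative and xenobiotic defence. Among the random lists, the median lay at percentile 100 for partial EMT, 99.97 for stem and progenitor genes and 99.9 for chemokines and cytokines. It lay at 99.7 for AP-1 factors, 40.9 for MHC class I and 15.8 for interferon response. Hypoxia and glycolysis lay at 0.35, proliferation at 0.18 and oxidative and xenobiotic defence at 0. These percentiles are a description and not a test.

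**Figure D3:**
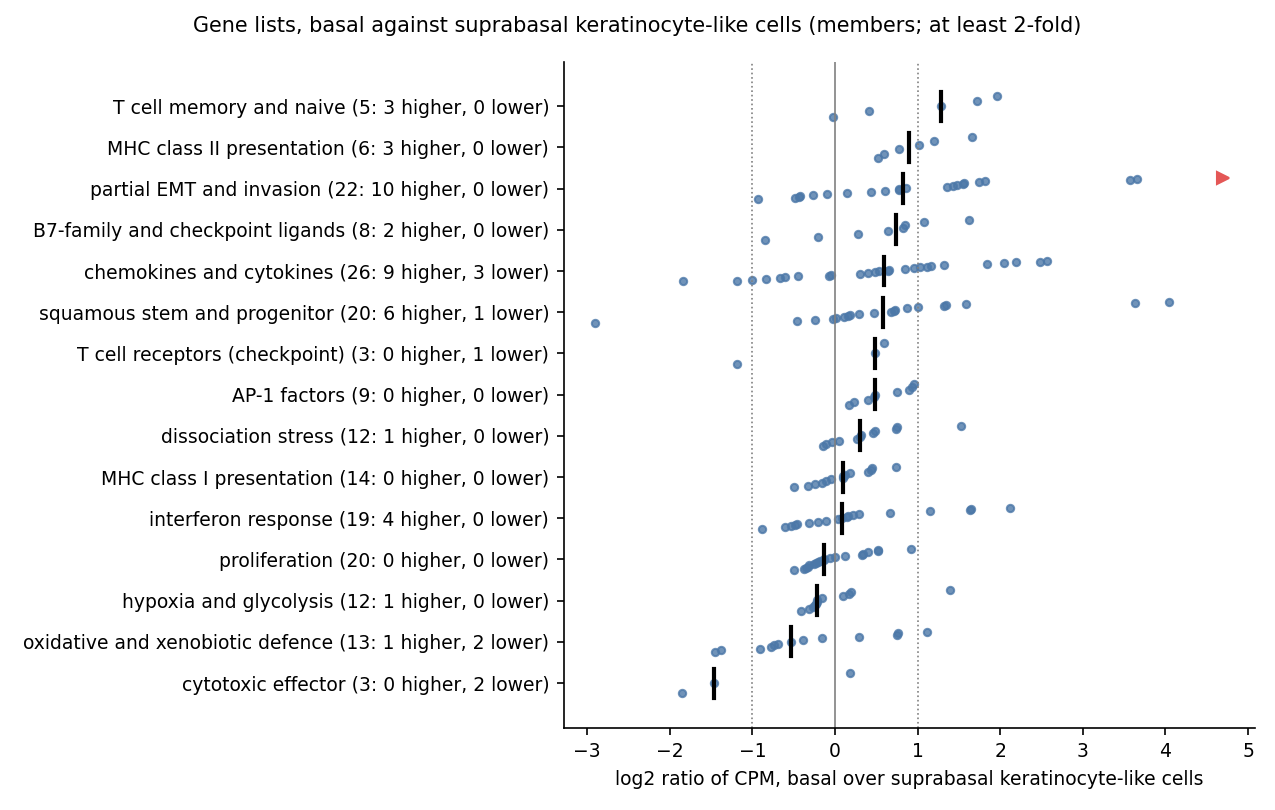
Log2 ratio of CPM in basal over suprabasal keratinocyte-like cells, each point 1 member of a list with at least 20 UMIs, each bar the list's median and the dotted lines a 2-fold difference; the triangle is Mmp9, a lower bound from 0 suprabasal UMIs. Partial EMT and invasion has 10 of 22 members at least 2-fold higher in basal cells.

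Whether cells in which the target was seen differed from the other basal cells was compared at 2000 UMIs per cell, between 31 cells with and 984 without a Cd276 UMI. Of 15 stem and progenitor genes, 2 were at least 2-fold higher with Cd276 and 0 lower, Cd34 (3.07, 0.601 to 9.85; 3 UMIs) and Igfbp5 (2.15, 0.908 to 4.38), and both intervals include 1. Of 19 partial EMT and invasion genes, Fn1, the gene of fibronectin (7.05, 1.74 to 21.4), and Pdpn (2.72, 0.535 to 8.63; 3 UMIs) were higher, and Cdh1 (0.441, 0.0529 to 1.62; 2 UMIs) and Mmp14 (0.305, 0.0367 to 1.12; 2 UMIs) lower; the counts were 2 higher and 1 lower of 15 at 1000 UMIs and 6 higher and 2 lower of 21 at 4000 UMIs. Of interferon response genes, 3 of 12 were higher and 1 lower, against 1 and 0 of 5 at 1000 UMIs and 0 and 2 of 14 at 4000 UMIs. Of 20 proliferation genes Tpx2 (3.64, 1.41 to 7.97) and Bub1b (2 UMIs) were higher and Ccnb1 (1 UMI) lower, and of 13 oxidative and xenobiotic defence genes Hmox1 (3.04, 1.35 to 6.02) was higher and 3 lower. The proliferation counts were 5 higher and 0 lower of 15 at 1000 UMIs and 1 and 1 of 20 at 4000 UMIs, and the oxidative defence counts 4 and 0 of 12 and 0 and 5 of 13. At 4000 UMIs the ratio of Fn1 was 2.24 (0.583 to 6.16) and that of Hmox1 0.334 (0.0401 to 1.23; 2 UMIs). Of 2 MHC class II genes, Cd74 was 14.1-fold (5.31 to 34.1) higher, from 8 UMIs against 18, but 7 of the 8 lay in 1 cell, so the interval understates the uncertainty. The MHC class II counts were 0 higher of 1 at 1000 and 3 of 4 at 4000 UMIs, and those of hypoxia and glycolysis 1 of 12 at 2000, 0 of 11 at 1000 and 4 of 12 at 4000 UMIs. Cd44 (1.06, 0.673 to 1.58), Bmi1 (0.705) and Sox2 (0.832, 0.302 to 1.84) were not 2-fold apart. The stem and progenitor counts were 4 higher and 2 lower of 13 at 1000 UMIs (12 cells with Cd276) and 0 higher and 1 lower of 16 at 4000 UMIs (37 cells). Of suprabasal cells, 0 of 217 had a Cd276 UMI at 2000 UMIs (interval up to 1.69%) and 4 of 195 at 4000 UMIs, 2.05% (0.562 to 5.17).

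How varied the keratinocyte-like cells were, and how far the clusters followed the sex of the animals, was described over 10 clusters, each against the other keratinocyte-like cells. In cluster 1 (basal, 270 cells), 11 of 22 partial EMT and invasion genes were higher and 0 lower, led by the matrix metalloproteinase genes Mmp10 (33.4, 19.1 to 62.9), Mmp9 (18.8, 14.0 to 25.9) and Mmp13 (16.8, 14.0 to 20.2). So were 5 of 12 hypoxia and glycolysis genes, among them Car9 (4.00, 3.21 to 4.99), Egln3 (3.55, 3.25 to 3.88) and Bnip3 (3.54, 3.18 to 3.94), while all 19 interferon response genes were lower. The latter rested on clusters 3 and 9 among the other cells, and without these 1 of 13 interferon response genes was higher in cluster 1 and 3 lower, a comparison added after the values were seen. Cd276 was 2.33-fold (1.77 to 3.06) higher in this cluster, at 19.3 CPM (15.5 to 23.8), with 1.78 (1.23 to 2.55) among Y-only and 2.90 (0.862 to 7.81) among Xist-only cells. The partial EMT count was 7 of 20 among Y-only and 12 of 20 among Xist-only cells. Mgarp and Ndufa4l2, genes outside the lists, were among the leading genes of cluster 1, so part of its hypoxia and glycolysis difference may be built in.

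In cluster 3 (basal, 181 cells), all 19 interferon response genes were at least 2-fold higher, with a median log2 ratio of 3.06. Cxcl9 (54.8, 28.5 to 118), a chemokine that attracts T cells, Ifit3 (26.8, 14.9 to 52.0) and Gbp2 (16.1, 11.4 to 23.1) led, and 7 of 14 MHC class I genes were higher, among them the regulator Nlrc5 (3.44, 2.48 to 4.72). Of 27 chemokines and cytokines 8 were higher and 5 lower, led by Cxcl5 (19.9, 15.6 to 25.7) and Ccl20 (6.78, 6.18 to 7.45), and 16 of 20 proliferation genes were lower. The cluster held 148 Y-only and 0 Xist-only cells, and among Y-only cells the 19 genes were all higher as well (median 2.76). Its clustering genes included other interferon-induced genes such as Oasl2 and Trim30a. Suprabasal cluster 9 (54 cells, 44 Y-only and 1 Xist-only) had 13 of 19 interferon response genes higher and 1 lower, with Rsad2 (6.79, 4.91 to 9.32) and Isg15 (5.89, 5.22 to 6.64) among them, and 14 of 20 proliferation genes higher.

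Cluster 4 (basal, 132 cells) had 19 of 20 proliferation genes higher, led by Aurkb (8.65, 7.14 to 10.5), Ccna2 (8.60, 7.42 to 9.98) and Top2a (8.46, 7.91 to 9.06); histone genes were among those that set it apart. Mki67 was at 574 CPM in cluster 4 and at 480 CPM in cluster 9. Cluster 6 (basal, 128 cells) had 8 of 9 AP-1 factors higher, such as Fosb (4.36, 4.19 to 4.52) and Atf3 (3.89, 3.73 to 4.05), and 9 of 12 dissociation stress genes, such as Nr4a1 (5.52, 5.06 to 6.02) and Egr1 (3.93, 3.78 to 4.08). It also had 11 of 27 chemokines and cytokines higher and 7 lower, with Ccl2 at 4.83 (4.57 to 5.11), and it held 43 of the 56 Lgr5 UMIs of the class (ratio 40.6, 21.4 to 82.3). Egr2, Egr3 and Egr4, relatives of the list gene Egr1 but outside the lists, were among the leading genes of cluster 6. Part of its AP-1 and dissociation stress difference may therefore be built in. Cluster 5 (basal, 131 cells, 95 Xist-only and 4 Y-only) had Lef1 19.7-fold (14.0 to 28.0) and Lgr6 4.47-fold (2.09 to 8.95) higher. Its Cd276 ratio was 0.403 (0.172 to 0.808; 8 UMIs), and 0.772 (0.277 to 1.885; 7 UMIs) among Xist-only cells. Cluster 2 (basal, 202 cells) had Igfbp5 4.09-fold (3.49 to 4.79) higher and 12 of 22 partial EMT and invasion genes lower.

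Of the suprabasal clusters, cluster 7 (105 cells) had Aldh3a1 6.47-fold (5.77 to 7.25) higher, 17 of 22 partial EMT and invasion genes lower and Cd276 at a ratio of 0.117 (0.0141 to 0.429; 2 UMIs). Cluster 8 (88 cells, 63 Y-only and 2 Xist-only) had Aldh1a3 13.9-fold (10.4 to 18.6) and Ccl4 8.03-fold (5.91 to 10.9) higher, with 3 of 12 hypoxia and glycolysis genes higher. The unnamed cluster 10 held 32 cells, all Xist-only. Tslp, a cytokine of barrier epithelium, was 345-fold (228 to 543) higher in it, as were 11 of 22 partial EMT and invasion genes such as Itga5 (7.74, 5.60 to 10.5) and Itgb6 (7.03, 4.65 to 10.3), with 5 lower. Clusters 3, 5, 8, 9 and 10 each drew over 95% of the cells with a sex call from 1 sex, so in them the sex of the animals and the cluster go together.

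**Figure D4:**
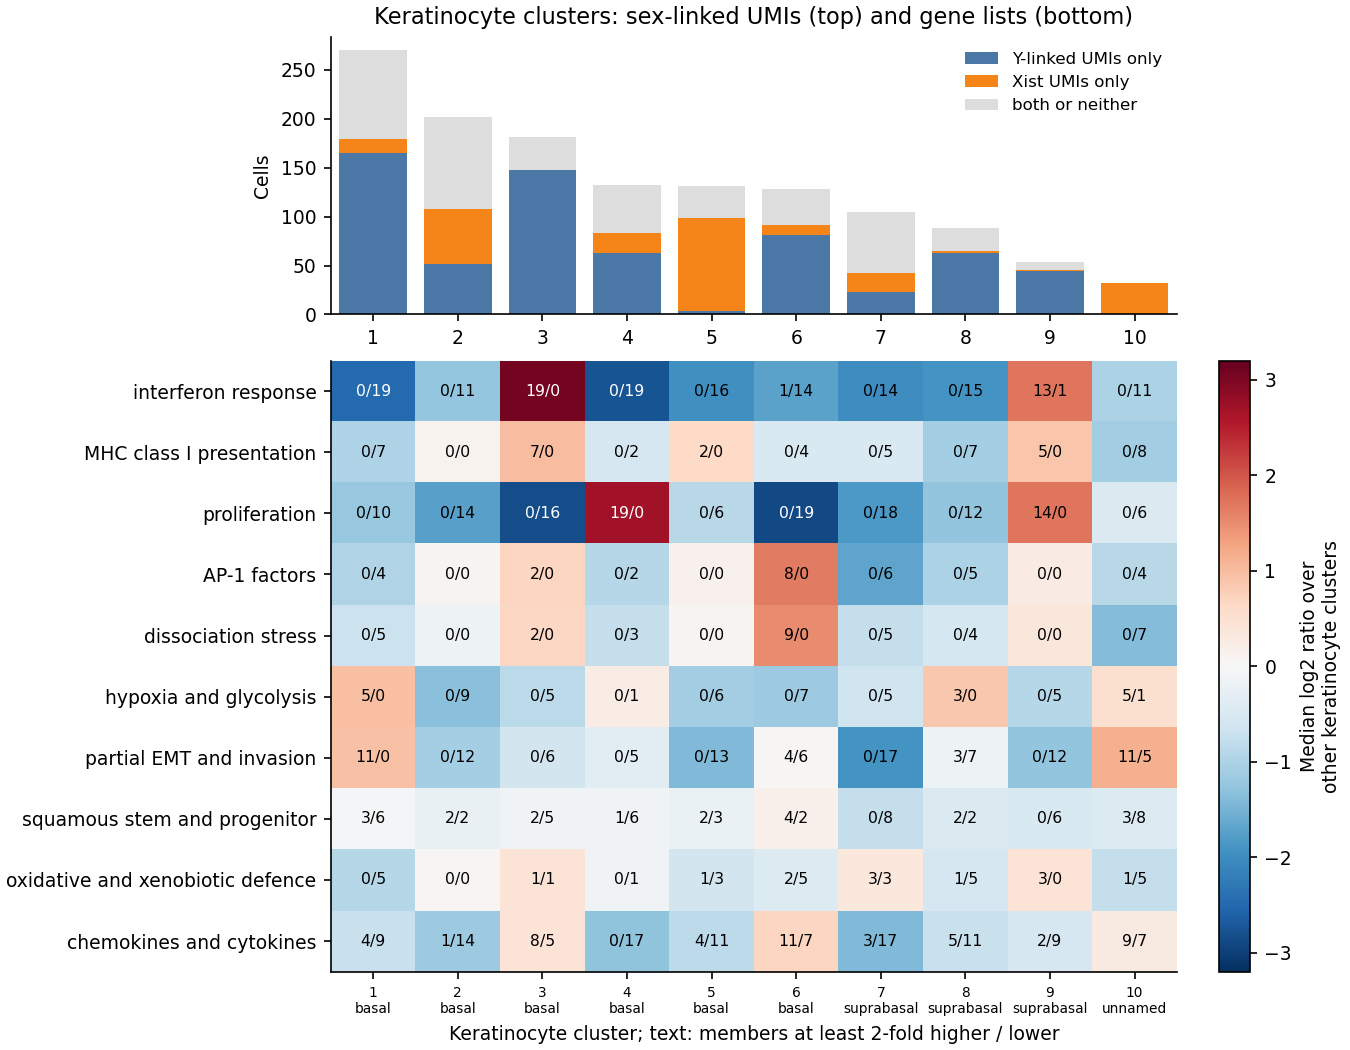
Top, cells per keratinocyte cluster by sex-linked UMIs; bottom, median log2 ratio of each gene list in a cluster over the other keratinocyte-like cells as colour, with the members at least 2-fold higher and lower as text. Cluster 3 has 19 of 19 interferon response genes higher, and cluster 4 has 19 of 20 proliferation genes higher.

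What states the T-like cells were in was read from 4 clusters of the 403 T-like cells, each against the other T-like cells. The γδ T-like cluster, of T cells with the γδ receptor, was the largest with 135 cells, 33.5% (28.9 to 38.3). It was higher in Pdcd1, the gene of PD-1 (3.25, 2.39 to 4.45; 301 CPM), in Cd226 (3.33, 2.18 to 5.19), in Cxcr6 (3.54, 3.02 to 4.16), in Gzma (3.43, 2.92 to 4.04) and in Prf1, the gene of perforin (19.1, 4.76 to 166; 2 UMIs in the others). Over the lists, 5 of 13 checkpoint and costimulatory receptors were higher and 5 lower, and 4 of 13 cytotoxic effector genes were higher and 6 lower. It had 0 Cd28 and 0 Ccl5 UMIs, at least 85.8-fold and 53.1-fold lower, and 13 of 14 interferon response genes were lower. The regulatory T-like cluster (79 cells, 19.6%, 15.8 to 23.8) had 5 of 13 checkpoint and costimulatory receptors higher and 2 lower, with Tnfrsf4 (12.2, 9.41 to 16.0), Cd27 (8.82, 5.45 to 14.6) and Tnfrsf18 (6.75, 4.92 to 9.30) highest and Pdcd1 at 0.182 (0.0722 to 0.382). Gzmb (2.14, 1.56 to 2.91), Il10 (8.56, 4.37 to 17.4) and 8 of 14 interferon response genes were higher in it, and 1 of 13 cytotoxic effector genes was higher and 8 lower. The CD4 T-like cluster (83 cells, 20.6%, 16.7 to 24.9) had 10 of 13 cytotoxic effector genes lower and 0 higher, with 0 Gzma UMIs, at least 70.6-fold lower.

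The remaining T-like cluster, of 106 cells (26.3%, 22.1 to 30.9), stayed unnamed, and had 8 of 13 cytotoxic effector genes higher and 2 lower. Ccl5 (59.1, 35.1 to 107), Ifng (36.6, 16.8 to 94.7) and Nkg7 (12.6, 9.41 to 17.2) led, and 7 of 14 interferon response genes were higher, with Ifit3 at 21.4 (7.26 to 85.3) and Cxcl10 at 9.02 (5.85 to 14.2). So were 3 of 4 MHC class II genes, which mark macrophages and dendritic cells: H2-Aa (8.20, 3.54 to 20.6), H2-Eb1 (7.29, 2.90 to 19.8) and Cd74 (2.59, 1.92 to 3.48). Free RNA was expected to add 10.1 of 82.6, 9.40 of 65.2 and 22.5 of 339 CPM of these, and whether myeloid cells in the same droplets added to this cluster was not tested. Tcf7 (7.29, 3.85 to 14.3) and S1pr1 (4.46, 2.58 to 7.77), genes of naive and memory T cells, and the costimulatory receptor Cd28 (3.39, 2.76 to 4.15) were also higher, and Tnfrsf9 (0.0985, 0.0535 to 0.167) and Havcr2 (0.151, 0.0599 to 0.318), receptors of activated T cells, were lower. This cluster held all 33 Cd8a UMIs and 74 of 77 Cd8b1 UMIs of T-like cells beside 38 of 146 Cd4 UMIs, counts looked up after its other values were seen. The planned comparison of CD8 T-like with other T-like cells had no value, since no cluster was named CD8 T-like. One was named at a minimum of 1000 UMIs (87 cells), at a mitochondrial limit of 10% (85 cells) and at a resolution of 2 (57 cells), with 8, 6 and 8 of 13 cytotoxic effector genes higher and 2, 3 and 2 lower, and 3 of 4 MHC class II genes higher in each.

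How the macrophage-like cells differed from the keratinocyte-like and the fibroblast-like cells in antigen presentation and checkpoint ligands was compared over 152 macrophage-like cells. All 7 MHC class II genes were higher than in keratinocyte-like cells, with Cd74 at 2412-fold (2045 to 2866) and H2-Aa at 2242-fold (1718 to 2983), and all 7 were higher than in fibroblast-like cells. Cd86, a ligand of CD28 and CTLA-4, was 1462-fold (616 to 4554) higher than in keratinocyte-like cells and, with 0 fibroblast-like UMIs, at least 88.5-fold higher than in fibroblast-like cells. Over keratinocyte-like cells, 9 of 12 B7-family and checkpoint ligands, 15 of 19 interferon response genes, 12 of 14 MHC class I genes and 6 of 6 cytotoxic effector genes were higher with 0 lower, and 21 of 33 chemokines and cytokines were higher with 6 lower. Stem and progenitor genes (2 higher, 11 lower of 20), oxidative and xenobiotic defence (3 higher, 9 lower of 13) and proliferation (0 higher, 16 lower of 20) had more members lower. Over fibroblast-like cells, Il1b (327, 172 to 716), Mmp13 (52.6, 32.1 to 92.6) and Cd274 (33.3, 10.95 to 165; 3 fibroblast-like UMIs) were higher, and 11 of 21 partial EMT and invasion genes were lower and 6 higher. The class was mixed: 40 of its cells were migratory dendritic-like, marked by Ccl22, Ccl17, Ccr7 and Fscn1, and 63 formed a shallow cluster (median 1079 UMIs) led by epithelial genes, with 36.7% of its RNA expected from empty droplets.

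Whether mesenchymal genes in the tumours lay in fibroblasts or in epithelium was compared between 118 fibroblast-like and 1323 keratinocyte-like cells. Of 26 partial EMT and invasion genes, 14 were higher in fibroblast-like cells, led by the transcription factors Twist1 (543, 297 to 1104) and Zeb1 (245, 150 to 423) and by Fn1 (225, 195 to 262), and 7 were lower, lowest Lamb3 (0.0194, 0.00529 to 0.0497) and Lama3 (0.0682, 0.0312 to 0.130), chains of the epithelial laminin. Of 29 chemokines and cytokines, 15 were higher and 7 lower, with Ccl8 (641, 304 to 1620) and Cxcl12 (136, 94.7 to 201) highest. Among the checkpoint ligands, 5 of 9 were higher, Vsir (224, 102 to 583), Cd47 (3.82, 3.45 to 4.23) and Pvr (3.38, 2.15 to 5.09) the most, and 0 lower. Of 20 stem and progenitor genes, 4 were higher and 9 lower. Igfbp5 (63.3, 58.0 to 69.1) and Cd34 (38.8, 33.8 to 44.6) were higher, while Sox2, with 0 fibroblast-like UMIs, was at least 22.9-fold lower. Proliferation genes (0 higher, 19 lower of 20) and hypoxia and glycolysis genes (0 higher, 9 lower of 12) were lower. Among Y-only cells the partial EMT counts were 12 higher and 7 lower of 23, and among Xist-only cells 11 higher and 7 lower of 26.

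Levels over all classes were read for the highest members of each list. Cd274 was highest in neutrophil-like cells (281 CPM, 238 to 330), followed by macrophage-like cells (121, 95.2 to 152), and Cd86 in macrophage-like cells (323 CPM, 279 to 371). Cd47, whose product restrains phagocytosis, was highest in lymphatic endothelial-like (644 CPM, 494 to 826) and fibroblast-like cells (525, 477 to 577). Neutrophil-like cells had the highest levels of the chemokine Cxcl2 (45419 CPM), of Il1b (13084 CPM), of Ccl4 (7129 CPM) and Ccl3 (6313 CPM). T-like cells led for Icos (983 CPM, 926 to 1042), Ctla4 (553, 510 to 598) and Tnfrsf9 (504, 463 to 547). Vim was highest in blood endothelial-like (7580 CPM) and mural-like cells (6155 CPM), and Cd44 in neutrophil-like cells (1329 CPM, 1234 to 1430). Keratinocyte-like cells led for Gsta4 (1128 CPM), Ldha (1074 CPM), Top2a (156 CPM) and Mki67 (154 CPM), which in empty droplets were at 635, 499, 93.2 and 65.3 CPM.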

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

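The tests of the interferon response pattern, of free RNA and of depth for Cd276 were chosen after the results had been seen, and those of the sex-linked clustering genes and of a few cells with many UMIs before. For the interferon response pattern, tests of immune cells and of sex replaced earlier ones whose outcomes had been seen: 4 of the 19 genes had a lower bound above the level of the highest immune class, and outside clusters 3 and 9 the Y-only over Xist-only median log2 ratio was 0.66 over 10 genes, 4 of them at least 2-fold higher. Apart from sex, read from Xist and Y-linked UMIs, no biological explanation was tested, because the design gives no groups within the library.

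The signal in data outside the comparisons was Gm42418, a gene that overlaps ribosomal RNA sequence (GRCm38 chromosome 17, 39846958 to 39848788), which made up 30.4% of the UMIs in the 39123 empty droplets of 200 to 450 UMIs, against 2.46% in cells and 7.89% in barcodes of at most 100 UMIs.

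In keratinocyte cluster 3, all 19 interferon response genes were at least 2-fold higher than in the other keratinocyte-like cells, and the cluster held 148 Y-only and 0 Xist-only cells. Immune cells captured in the same droplets would have to supply, for each gene from the class where it needs least, 4.28% (Rsad2) or more of the cluster's RNA, with a median of 53.8% over the 19 genes. The highest share seen, from Il17a, Vim, Emb, Rgs1 and Srgn of T-like cells, was 2.68%, and all 19 genes needed more. Both shares rest on class averages. Of 3407 Il17a UMIs, 2962 lay in the γδ T-like cluster, where 13 of 14 interferon response genes were lower. Only 2 lay in the unnamed T-like cluster, where 7 of 14 were higher. Capture of T-like cells of that cluster alone was therefore not tested. Free RNA would leave the genes at or below the empty droplets, and 19 of 19 had a lower bound above them. Sex as the only cause would leave no difference among Y-only cells, where the median log2 ratio was 2.76 with 19 of 19 genes higher. Other interferon-induced genes partly defined the cluster, so a difference in this direction was built in. The test cannot decide whether sex played a part. A single animal or tumour, or a local signal that reached its cells, may lie behind the pattern and stays untested, since the cells carry no label of their animal.

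Several keratinocyte clusters held cells of nearly 1 sex, with 63.7% of the 892 cells with a sex call in clusters of at least 90% 1 sex. Xist and the Y-linked genes among the clustering genes could give such clusters, but with these genes left out 55.6% of the cells still lay in such clusters, 5 of 10 clusters against 6 before. Y-only cells were 72.1% of the cells with a call. Differences between the sexes, between animals and between tumours in the programmes themselves stay open.

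Cd276 was higher in blood endothelial-like than in keratinocyte-like cells. Free RNA would bring the level to at most the 7.03 CPM of empty droplets, and its lower bound was 40.3 CPM. Of the 115 UMIs, 38 lay in 5 cells, and without these the ratio was 3.39 (2.59 to 4.41), still above 1. With every cell thinned to 1000 UMIs the ratio was 3.61 (1.40 to 9.11). CPM already divides by the UMIs of each class, so thinning could not have shown depth as the cause, and no conclusion is drawn from it. The pattern may be a property of endothelial cells in these tumours, as a hypothesis from 1 library, and whether the antibody altered it was not testable without counts of the control library.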

How the results depend on the processing

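Over 9 results, 145 values were computed under alternatives, 0 of the ratios whose interval excludes 1 changed direction, 127 stayed within the interval of the main value (for counts, within 1.5-fold) and 18 moved beyond it; the cause was not tested where none is named. The free RNA profile of 200 to 450 UMIs, the sex-limited sets and the omission of single clusters were chosen after the data were seen. The keratinocyte-like share was 42.2% at a minimum of 1000 UMIs, 36.4% at a mitochondrial limit of 10%, 28.6% without the test against free RNA and 40.6% with the profile of 200 to 450 UMIs. The T-like share was 5.66% without that test, 7.43% at a resolution of 2 and 8.57% with that profile; without the test, 7034 barcodes counted as cells. A CD8 T-like cluster of 87, 85 and 57 cells appeared at the 1000-UMI minimum, the 10% limit and the resolution of 2, and of 0 cells in the main settings and the other 5 runs. The endothelial-like over keratinocyte-like Cd276 ratio was 2.87 as a mean of each cell's CPM, 3.61 thinned to 1000 UMIs, 6.79 among Xist-only cells and 5.90 without keratinocyte cluster 1, within a range of 2.87 to 6.79. The basal partial EMT count of 10 was 6 at the 1000-UMI minimum, 4 without keratinocyte cluster 1 and 14 without keratinocyte cluster 8. The stem and progenitor count in Cd276-detected cells, 2 at 2000 UMIs, was 4 at 1000 UMIs (12 cells) and 0 at 4000 UMIs (37 cells). The fibroblast-like ratio, whose interval includes 1, lay on both sides of 1 (0.874 to 1.85). The basal over suprabasal Cd276 ratio ranged from 2.06 to 4.33 over 23 alternatives, all within the interval of its main value. The basal stem and progenitor count ranged from 4 to 9 over 24 alternatives, all within 1.5-fold of its main value. Leaving out the unnamed cluster 10, which is neither basal nor suprabasal, could not change these results or the basal partial EMT count. Its values are nevertheless among the 127. The basal over suprabasal ratio thinned to 1000 UMIs had no value, with 0 suprabasal UMIs, and the CD8 T-like comparison had no main value to compare with. Cd276 had 429 UMIs in 319 of 3459 cells.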

Other observations

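The unnamed macrophage-like cluster of 49 cells, clustered after the class had been named, was led by Arg1, F13a1, Pf4, Ccl3 and Ccl4, and had a median of 5165 UMIs. The migratory dendritic-like cluster of 40 cells had a median of 6142 UMIs. Klrd1 was among its leading genes.

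The unnamed clusters of the first level were of 133 cells (median 1374 UMIs, 26 Xist-only and 7 Y-only), of 86 cells (median 878 UMIs, led by Dcpp3, Dcpp1 and Gm42418, with 45.1% of the RNA expected from empty droplets) and of 16 cells (led by Psca, median 9184 UMIs). Among named clusters, that share was 51.5% in a neutrophil-like one of 88 cells (median 769 UMIs). In a salivary-like cluster of 83 cells (median 1261 UMIs) it was 31.4%. Il17a, the gene of the cytokine interleukin-17A, had 3407 UMIs in T-like cells, of which 2962 lay in the γδ T-like cluster (6659 CPM, 6421 to 6903) and 431 in the CD4 T-like cluster (1660 CPM, 1507 to 1824), a gene looked up after the clusters were seen. The 4 T-like clusters differed in free RNA, from 14.0% of the RNA expected from empty droplets in the γδ T-like cluster to 23.5% in the unnamed one.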
